A study of Lactuca sativa with 24 samples.

How the data were processed

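Leaves of lettuce (Lactuca sativa) of the varieties Luna bionda and Falstaff were profiled by RNA sequencing in 24 libraries, 3 in each of 8 groups. Groups, treatments and replicate numbers were taken from the sample labels. The labels describe Trizol-based RNA extraction, amplification of cDNA, Nextera XT libraries and paired-end NovaSeq sequencing, and give the molecule as polyA RNA. No label says whether libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical in part.

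Per the submitters' processing notes, reads were aligned with STAR and counted per gene with featureCounts 1.6.3. The version of STAR, the genome build, the annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here. The authors deposited 7 tables of normalized signal per gene, each with 6 libraries normalized together. The authors also deposited, for each of these tables, a log2 fold change with its standard error, and a p-value with an adjusted p-value, per gene. Per the file headers, the columns of these tables have the names that DESeq2 uses. No column belonged to another sample.

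The deposited normalized signal of each library was made of whole multiples of a single step, so that whole reads could be recovered. At a relative tolerance of 0.001, 100.0% of the values came out whole. For the 18 library columns that repeated a library already read from another table, the values differed between tables by a constant, with a largest relative spread of 1.7e-14. The recovered reads of the 24 libraries were joined into a single set of 31499 genes. Of these identifiers, 31073 matched the RefSeq gene table of assembly Lsat_Salinas_v11 and 426 did not. That table was used for the biotype of a gene, for its place in the nuclear, plastid or mitochondrial genome, and for the order of neighbouring genes. No coordinate is printed, since the authors' build is not given. For 30879 genes the symbol is a locus identifier with no product name. The lists of phenylpropanoid, flavonoid, light-signalling, DNA-repair, photosystem and similar genes that were fixed before the data were examined matched on product names, and so none of them could be filled. For the same reason, the named genes are limited to 2 that were higher and 2 that were lower per comparison. They are those with the largest change among genes past an adjusted p of 0.05, with a mean log2 level of at least 6 and no overlap between the groups in any library.

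The columns of the deposited tables were matched to samples by the batch tag in the labels. By the labels, these columns do not hold the groups that the names of the tables give. In Falstaff the sets of 3 libraries are those of the labels, but under other names. In Luna bionda the sets themselves differ, because 1 library of day 6 visible light and 1 library of UVB for 7.5 h per day change places with others. All groups here follow the labels, and whether the labels or the table names are right was not settled. The variety of each library is the same under both. The conditions of the Luna bionda comparisons and of those between varieties hold for the labels only. The Falstaff UVA group is given as UVA by its title and treatment, whereas the table named in its description is called UVB2. The design had planned each comparison with day 0 within a deposited table. Only Falstaff at day 6 under visible light against day 0 lies within a table by the labels, and so all comparisons were run on the joined reads.

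The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(reads divided by a median-of-ratios size factor + 1). Genes with a mean normalized value of at least 10 over the fitted libraries were tested, and calls were made at a Benjamini-Hochberg adjusted p of 0.05. Comparisons with day 0 and between varieties in a single condition used the 6 libraries compared. Comparisons within day 6 used all 12 libraries of the variety, and the interaction of variety and UVB used all 24. Fold changes are on the scale with a pseudocount of 1, which understates changes of low genes. Alternatives planned before the data were examined were TMM scaling, pseudocounts of 0.5 and 5, no filter, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, a replicate block, a term for the start of the batch tag, another set of fitted libraries, and the omission of each library in turn. The tags start with 107 or 109, called the lower and the upper number series here. The labels name no series. Alternatives chosen after seeing the data were the omission of the 6 shallow libraries, with limma and with edgeR, and limma sample weights. The varieties at day 6 under visible light, at UVB for 2.5 h per day and over all 24 libraries, and Falstaff under UVA against UVB, were also compared only after the data had been seen.

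Same-numbered libraries were checked for pairing by the correlation, across genes, of their deviations from the group means. In 1 comparison, Falstaff at UVB for 2.5 h per day against day 0, all 3 correlations exceeded 0.1 (0.584, 0.507 and 0.507). Replicate 1 is shallow in both of these groups, and the highest correlation between different numbers was 0.523. The count of calls with the block was 0 there too. In no other comparison did every pair exceed 0.1. The chi-square per degree of freedom over genes with at least 20 reads was 38.7 or more in the 24 pairs of libraries within a group and 6.35 or more in all 276 pairs, so that each pair differed by more than sampling noise.

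The test was tried on simulated data in which 200 genes were changed, 50 for each fold size. The changed genes were drawn from those with a mean normalized value of at least 50, so that the shares do not cover lower genes. Counts were drawn independently, with a single dispersion per gene and the size factors of the real libraries. Libraries that stand apart in many genes were not simulated, so that the shares may differ from what the real test recovers. For Luna bionda at day 6 under visible light against day 0 (22271 genes), 42% of the genes changed 4-fold and 94% of those changed 8-fold were called. For Luna bionda UVB at 2.5 h per day against visible light (21780 genes), the shares were 10% and 64%. For Falstaff UVB against visible light (19158 genes) they were 2% and 10%, and for the interaction (21052 genes) 0% of genes changed 8-fold and 18% of those changed 16-fold were called. For Falstaff UVA against day 0 (17379 genes), 0% of the genes changed 16-fold were called. For the varieties at day 0 (21635 genes), the shares were 10% at 4-fold, 36% at 8-fold and 76% at 16-fold. In that simulation 12 unchanged genes were also called. The other simulated comparisons gave 0 to 9 calls of unchanged genes. The share of false calls was thus not shown to stay at the nominal level of the adjusted p. Intervals of shares are 95% Wilson or exact binomial intervals and cover counting error only. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.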

Results

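Baby leaves of 2 lettuce varieties, Luna bionda and Falstaff, were sampled at day 0 and after 6 days under LED lamps. At day 6 the leaves had received visible light alone or visible light with UV at 0.4 W per square metre. In both varieties UVB was given for 2.5 h per day. Luna bionda was also given UVB for 7.5 h per day, and Falstaff was given UVA for 7.5 h per day. Each of the 8 groups held 3 libraries. The comparisons asked which transcripts differed between the varieties, over the 6 days, and with UV in each variety.

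The 24 libraries were of 2 kinds. In 18 libraries between 12072410 and 43276819 reads fell in genes. In the other 6 libraries the number was between 464282 and 1036697 reads, and the median of the deep libraries was 35.3 times that of the shallow ones. These shallow libraries were Luna bionda at UVB for 7.5 h replicate 1, Falstaff day 0 replicate 1, Falstaff UVB replicate 1, Falstaff UVA replicates 1 and 3, and Falstaff visible light at day 6 replicate 2. All 6 carried batch tags of the lower of the 2 number series in the labels, as did 4 of the deep libraries. Plastid genes took between 4.47% and 11.7% of reads in the shallow libraries and between 0.000758% and 0.0078% in the deep libraries. Mitochondrial genes took 1.17% to 2.78% against 0.00113% to 0.00284%. Ribosomal RNA genes took 3.19% to 11.6% against 0.000696% to 0.00731%, and small nucleolar RNA genes 1.14% to 4.38% against 0.0217% to 0.062%. The long noncoding RNA LOC111914492 took 5.81% to 18.9% of reads in the shallow libraries. Its share did not exceed 0.0244% in any deep library. The plastid gene psbA, which encodes the D1 protein of photosystem II, was the gene with the most reads in Falstaff UVB replicate 1 (8.28% of reads) and in Falstaff UVA replicate 3 (6.77%).

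**Figure D1:**
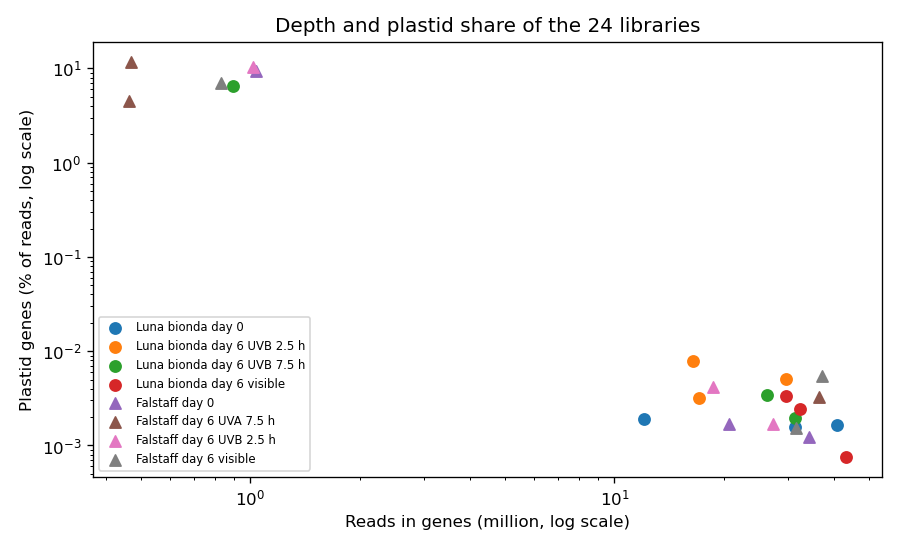
Reads in genes (log scale) and the share of reads in plastid genes (percent, log scale) for each of the 24 libraries, with circles for Luna bionda, triangles for Falstaff and a colour for each group. The 6 libraries with at most 1036697 reads have plastid shares of 4.47% or more, and the 18 others have shares of at most 0.0078%.

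Across genes, the Spearman correlation between libraries of a group ranged from 0.492 to 0.972, and the pairs with a shallow library were the lowest. Among the 18 deep libraries, the closest library was of the same variety in 18. It was of the same group in 5 of the 17 that had another deep library of their group. The mean correlation of deep Luna bionda libraries within a group was 0.916, and between groups it was 0.906. In Falstaff the means were 0.944 within and 0.934 between groups. Neither difference exceeded that of random sets of the same sizes (permutation test, one-sided, 100000 permutations, p = 0.181 in Luna bionda and p = 0.209 in Falstaff, adjusted p = 0.262 in both over 4 tests). Genes are not independent replicates, and the permuted units were libraries. Luna bionda UVB 2.5 h replicates 2 and 3 had a correlation of 0.946 with each other and of 0.827 and 0.854 with replicate 1. Replicate 1 was closest to Luna bionda UVB 7.5 h replicate 2 (0.97).

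**Figure D2:**
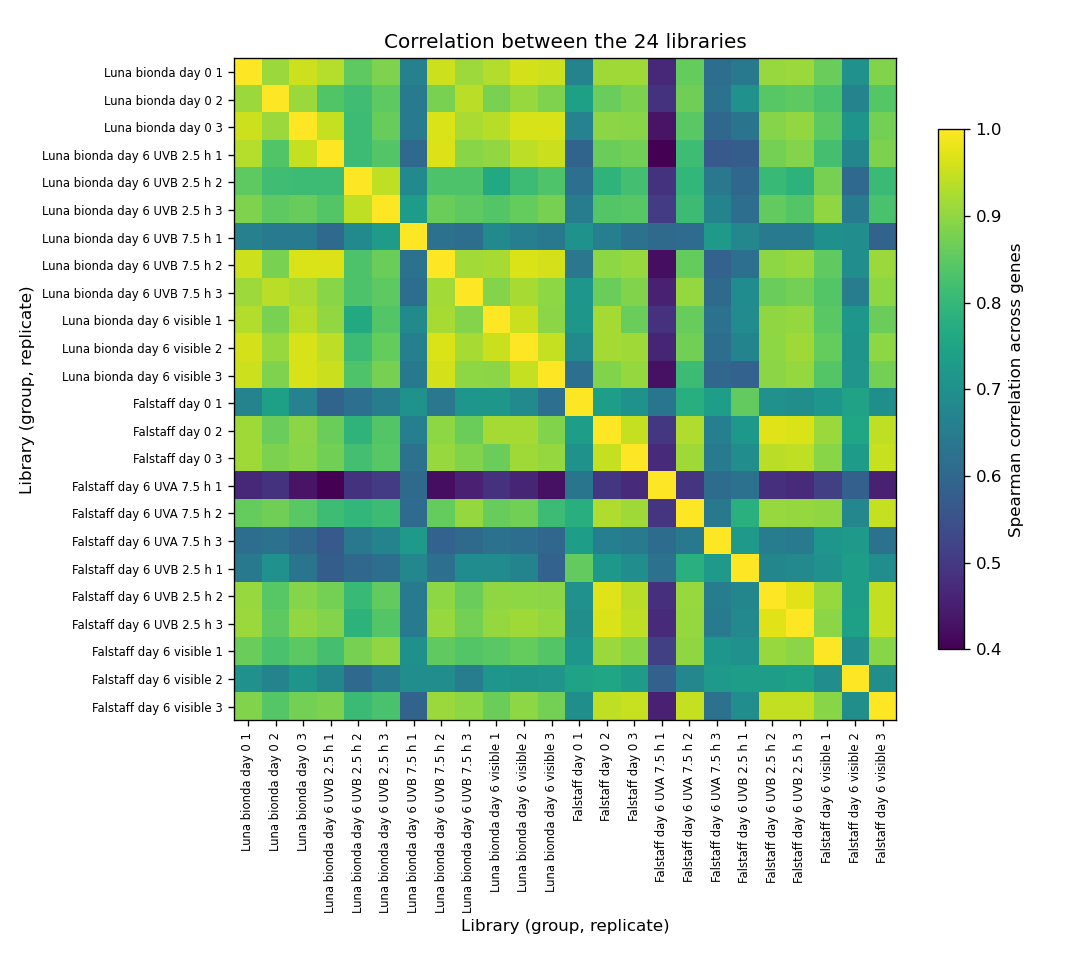
Spearman correlation across 21052 genes between all pairs of the 24 libraries, ordered by variety, group and replicate, on a colour scale from 0.4 to 1. The rows and columns of the 6 shallow libraries are darker than the rest, and Falstaff UVA replicate 1 reaches only 0.492 with replicate 2 of its own group.

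In Luna bionda, no gene passed the test between day 6 under visible light and day 0. With limma 0 of 22271 genes were called, the smallest adjusted p was 0.95, and 614 genes had an unadjusted p under 0.05 where 1114 would be expected by chance. Leaving out single libraries moved the 614 to between 217 and 1339, with 0 calls each time. The edgeR test called 0 genes and DESeq2 called 3. The median standard error of a log2 fold change was 0.43, and the groups did not overlap in 8.6% of genes, where chance gives 10%.

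UVB for 2.5 h per day in Luna bionda was compared with visible light at day 6 to ask which genes responded to UVB. All 3 UVB libraries carried batch tags of the lower number series and all 3 visible light libraries those of the upper one, so that UVB and tag series cannot be told apart between these groups. Here 0 of 21780 genes were called with limma, with a smallest adjusted p of 0.52. An unadjusted p under 0.05 was found for 1971 genes, where 1089 would be expected. The spread in this fit includes the shallow UVB 7.5 h library. With only the 2 compared groups fitted, 2727 genes were under that p. Without the shallow library 3888 were, with 0 calls in both fits. The groups did not overlap in 18.0% of genes, against 10% by chance. The edgeR test called 0 genes, and DESeq2 called 599, of which 531 were higher with UVB. A batch tag term rests on the other groups of the variety, day 0 and UVB for 7.5 h, and the lower-series library of the latter is shallow. With this term limma called 0 genes, with 4306 under an unadjusted p of 0.05 and a median log2 fold change of 0.35 instead of -0.05. These values mix tag series with depth. Against day 0, limma called 0 of 21474 genes, with a smallest adjusted p of 0.28 and 2599 genes under an unadjusted p of 0.05. The edgeR test called 0 and DESeq2 714. Both limma counts of 0 calls, against visible light and against day 0, rested on replicate 1 of the UVB group. Without it, limma called 520 genes against visible light (360 higher and 160 lower) and 1992 against day 0 (1132 higher and 860 lower). UVB replicates 2 and 3 correlated at 0.883 and 0.904 with the unexposed Falstaff visible light replicate 1. Their mean correlations with Luna bionda day 0 and visible light were lower, 0.832 and 0.876. These 520 and 1992 genes are thus not read as a response to UVB.

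UVB for 7.5 h per day in Luna bionda gave 0 calls with limma and with edgeR against visible light (327 and 765 genes under an unadjusted p of 0.05) and against day 0 (150 and 481 genes). DESeq2 called 14 and 8 genes. Leaving out single libraries moved the 327 genes against visible light to between 127 and 2349, with 0 limma calls each time. The highest value was without replicate 2 of the 7.5 h group. Between the 7.5 h and 2.5 h exposures, limma and edgeR called 0 genes, with 1437 and 1873 under an unadjusted p of 0.05, and DESeq2 called 56. Tag series and exposure were partly confounded here, with 3 libraries of the lower series at 2.5 h and 1 at 7.5 h, and with a batch tag term 0 genes were called, 6422 had an unadjusted p under 0.05 and the median log2 fold change was -0.30 instead of -0.12. Without replicate 1 of the 2.5 h group limma called 11 genes. The 7.5 h group held 1 shallow library, which was also its only library of the lower series, so that the batch tag values mix tag series with depth.

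In Falstaff, limma and edgeR called 0 genes in each comparison of conditions. UVB for 2.5 h per day against visible light had 30 of 19158 genes under an unadjusted p of 0.05 with limma and 117 with edgeR, and DESeq2 called 1 gene. Each of these 2 groups held a shallow library. The median standard error was 1.31 on the log2 scale. It rests on a spread shared over all 12 Falstaff libraries, the shallow UVA libraries included. With only the 2 groups fitted, limma called 0 of 20550 genes, with 101 under an unadjusted p of 0.05. The tags of the deep UVB libraries stand apart from all others of the upper series. UVB and this run of tags thus cannot be told apart among the deep Falstaff libraries, and the batch tag term does not separate them. Against day 0, visible light at day 6 had 131 genes under an unadjusted p of 0.05 with limma and 209 with edgeR, and UVB had 67 and 91. DESeq2 called 0 in both.

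UVA for 7.5 h per day in Falstaff had 1517 genes under an unadjusted p of 0.05 against visible light with limma and 308 with edgeR, and 219 and 240 against day 0. DESeq2 called 0 and 9 genes. In the UVA group 2 of the 3 libraries were shallow, and without the deep one, replicate 2, limma called 1300 genes against visible light, of which 1273 were lower. The median log2 fold change of all genes was -0.88 in that fit, -0.59 with all libraries (-0.18 with edgeR) and 0.02 without the shallow libraries. The scaling holds this median near 0 where few genes lack reads, so that the fit of deep libraries could not show a downward shift. Without the shallow libraries edgeR called 371 genes against day 0, 346 higher and 25 lower, with a single UVA library. UVA against UVB, a comparison chosen after the data had been seen, gave 0 calls with limma and edgeR (1544 and 454 genes under an unadjusted p of 0.05), 8 with DESeq2, and 1364 with limma without UVA replicate 2. All 6 pairs of Falstaff groups thus gave 0 calls with limma. This count holds whether the groups take the labels' names or those of the authors' tables. Of genes changed 8-fold in simulated data, only 0% to 14% were called in the Falstaff pairs simulated. UVA against UVB was not simulated. The 0 calls thus do not separate low power from no response.

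The response to UVB for 2.5 h per day was not shown to differ between the varieties. The interaction gave 0 of 21052 genes with limma, where 858 had an unadjusted p under 0.05 and 1053 would be expected. The edgeR test called 0 genes, with 1704 under that p, and DESeq2 called 240. Without the 6 shallow libraries, limma and edgeR called 0 of 22692 genes, but 4191 and 4393 were under that p. The confounding of UVB with tag series in Luna bionda carries over to the interaction, as do the separate tags of the deep Falstaff UVB libraries. With a batch tag term 0 genes were called, 3727 had an unadjusted p under 0.05 and the median log2 value of all genes was 0.51 instead of -0.12. All 6 shallow libraries were of the lower series, so that these values mix tag series with depth. Without Luna bionda UVB replicate 1, limma called 10 genes. The median standard error of the interaction was 1.68 on the log2 scale, and so only large differences were detectable at this depth.

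The varieties differed at day 0 as labelled. By the names of the authors' tables, these Luna bionda libraries would be day 6 visible light and these Falstaff libraries UVB. A difference of treatment within this contrast is thus not excluded. Of 21635 genes, 287 passed the limma test, 147 higher and 140 lower in Luna bionda, and all 287 differed at least 2-fold. Simulated data for this contrast gave 12 calls of unchanged genes, so that some of the 287 may be false. The protein-coding gene LOC111895045 had 12080 ± 2392 normalized reads in Luna bionda and 6.28 ± 7.05 in Falstaff (SD, n = 3 each), a log2 fold change of 11.39 (SE 0.89, limma adjusted p = 0.00516). LOC111897350 had 11890 ± 2150 against 399 ± 289, a log2 fold change of 5.40 (SE 0.79, limma adjusted p = 0.023). In the other direction, LOC111879914 had 32.1 ± 48.7 normalized reads in Luna bionda and 28550 ± 4788 in Falstaff, a log2 fold change of -11.13 (SE 1.08, limma adjusted p = 0.00694). LOC111886693 had 7.13 ± 6.22 against 12670 ± 7241, a log2 fold change of -11.07 (SE 0.99, limma adjusted p = 0.00694). Among called genes 149 were long noncoding RNAs, which is 8.22% of those tested, against 0.696% of other genes (Fisher's exact test, two-sided, p = 1.71e-83, adjusted p = 6.84e-83 over 8 tests). That test takes genes as independent, which genes measured in the same libraries are not, so that its p-value may be too small. Called genes of this biotype were divided evenly, 73 higher and 76 lower in Luna bionda. Protein-coding genes gave 138 calls, 0.712% of those tested.

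The number of genes called at day 0 depended on single libraries. Without the shallow Falstaff replicate 1 it was 667, and all 287 genes were among them. Without Falstaff replicates 2 and 3 it was 47 and 58, and without Luna bionda replicates 1, 2 and 3 it was 4, 7 and 0. The edgeR test called 397 genes and DESeq2 969, including 286 of the 287. The batch tag term gave 501 calls and kept all 287.

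The same comparison was then made in libraries that were not used at day 0. At day 6 under visible light 228 genes differed between the varieties with limma, 119 of them lower and the rest higher in Luna bionda. Of the 287 genes of day 0, 286 had the same direction there. In Luna bionda, 96 genes were higher at both times, where independent lists would share 0.752, and 84 were lower at both, against 0.79. With UVB for 2.5 h per day 209 genes differed, 99 higher and 110 lower. All 3 Luna bionda libraries there were of the lower tag series, against 1 of 3 in Falstaff, and a batch tag term gave 6281 calls, 3990 higher and 2291 lower. This term rests on the Falstaff libraries alone, whose lower-series library is shallow, so that it mixes tag series with depth. The tags of the deep Falstaff UVB libraries also stand apart from the others of the upper series. Of 281 day 0 genes tested with UVB, 275 had the same direction, and 79 genes were higher and 82 lower in both, against 0.678 and 0.748. In all 3 conditions 68 genes were higher and 63 lower, and no gene was called in opposite directions. LOC111895045 was again higher in Luna bionda at day 6 under visible light (log2 fold change 13.43, limma adjusted p = 0.000821), with 9.42 under UVB (limma adjusted p = 0.0676). LOC111886693 was lower in both (-9.92, limma adjusted p = 0.0205, and -11.88, limma adjusted p = 0.00586), as was LOC111879914 (-9.21, limma adjusted p = 0.0313, and -8.16, limma adjusted p = 0.0243). LOC111897350 was higher under visible light (7.70, limma adjusted p = 0.0287), and its value under UVB was 2.62 (limma adjusted p = 0.55). Leaving out any Luna bionda library of visible light gave 0, 1 and 0 calls. Leaving out Falstaff replicates 1, 2 and 3 gave 59, 642 and 50. Under UVB, leaving out Luna bionda replicate 2 or 3 gave 0 calls, and leaving out Falstaff replicates 1, 2 and 3 gave 473, 3 and 8.

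**Figure D3:**
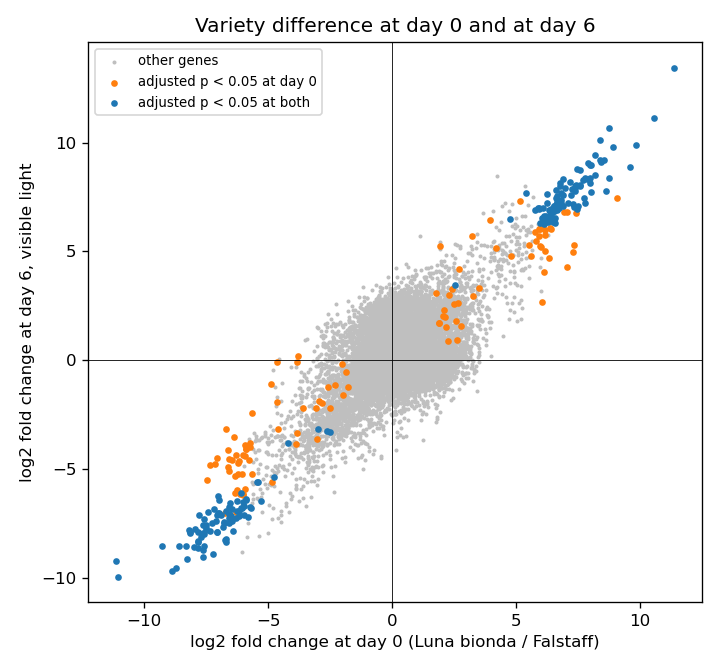
Log2 fold change of Luna bionda over Falstaff at day 0 (horizontal axis) and at day 6 under visible light (vertical axis) for 21101 genes, with genes called at day 0 only in orange and at both times in blue. The blue points, 96 higher and 84 lower in Luna bionda, lie where both fold changes have the same sign.

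Over all 24 libraries, 1175 of 21052 genes differed between the varieties with limma, 608 higher and 567 lower in Luna bionda. This fit pooled the conditions, with no term for day or light. UVB for 7.5 h per day was given only to Luna bionda and UVA only to Falstaff. These treatments are thus partly confounded with variety here. The median log2 fold change of all genes was 0.32 in this fit, and -0.01 without the 6 shallow libraries, of which 5 were Falstaff. Without them 2376 genes were called, 999 higher and 1377 lower, and 955 of the 1175 genes stayed called in the same direction. The edgeR test called 2269 genes and DESeq2 3410.

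Some genes had reads in 1 variety only. In the 11 deep Luna bionda libraries, 67 genes had at least 10 reads in each library and 0 reads in all 7 deep Falstaff libraries, which held 206042995 reads. Conversely, 117 genes had at least 10 reads in each deep Falstaff library and 0 in the deep Luna bionda libraries, which held 310210645 reads. Of these genes 53 and 85 were long noncoding RNAs, and 14 and 31 were protein-coding. The long noncoding RNA LOC111886953 had 130.0 ± 31.6 CPM (reads scaled to the library total) in Luna bionda (SD, n = 11), at least 8929-fold higher than a floor of 3 reads over the Falstaff group. The long noncoding RNA LOC111917322 had 25.0 ± 9.4 CPM in Falstaff (SD, n = 7), at least 2590-fold higher than the floor of the Luna bionda group. None of 1000 random divisions of the deep libraries into sets of these sizes gave such a gene. Both examples were chosen after their values were seen, as those with the highest mean CPM in each variety.

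The authors' deposited tables of differential expression list 477 genes with an adjusted p under 0.05 for their comparison of the varieties. The authors' deposited tables for Luna bionda list 60, 92 and 71 such genes, of which 22, 19 and 18 are organelle genes, and those for Falstaff list 1, 1 and 3. By the labels, the 3 Luna bionda tables and the variety table share a set that mixes replicates 2 and 3 of visible light at day 6 with the shallow replicate 1 of UVB for 7.5 h per day. The Luna bionda and variety counts thus do not answer the comparisons of the labels. The Falstaff counts of 1, 1 and 3 belong, by the labels, to UVA, day 0 and UVB, each set beside visible light at day 6.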

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

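Omission of the shallow libraries, sample weights and all values of the 4 added comparisons were chosen after seeing the data. Of 328 values under an alternative, 262 stayed within 1.5 times the main count. For the 13 comparisons with 0 calls, 216 of 240 alternatives also gave 0. The cause of the other changes was not tested.

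Comparisons with 0 calls in limma. DESeq2 gave 3 genes for Luna bionda visible light against day 0, 714 for UVB 2.5 h and 8 for UVB 7.5 h against day 0, 599, 14 and 56 for the Luna bionda contrasts within day 6, 9 for Falstaff UVA against day 0, 1 for Falstaff UVB against visible light, 8 for UVA against UVB and 240 for the interaction. Omitting single libraries gave 0 to 1992 genes for Luna bionda UVB 2.5 h against day 0, 0 to 520 against visible light, 0 to 11 for UVB 7.5 h against 2.5 h, 0 to 10 for the interaction, 0 to 1300 for Falstaff UVA against visible light and 0 to 1364 against UVB. Sample weights gave 1016, 5088, 773 and 4514 genes for the first 4 of these and 1 for Falstaff UVB against day 0. The edgeR test without shallow libraries gave 371, 1 and 5 for Falstaff UVA against day 0, visible light and UVB, where the UVA group was then a lone library assumed to vary like the others.

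Variety comparisons. At day 0, at day 6 under visible light and at UVB 2.5 h, DESeq2 gave 969, 1029 and 2064 genes, the batch tag term 501, 521 and 6281, the fits without shallow libraries 667, 642 and 473, and sample weights 1745, 1427 and 5539. In each of these comparisons the Falstaff library of the lower tag series was shallow, so that the batch tag counts mix tag series with depth. Omission of single libraries gave 0 to 667, 0 to 642 and 0 to 473. The edgeR test gave 417 under visible light, and without shallow libraries 725 at day 0 and 570 under visible light. The fit of all 24 libraries gave 352 at UVB. Over all 24 libraries, edgeR gave 2269, DESeq2 3410, the batch tag term 1958, omission of the shallow libraries 2376 (edgeR 2230) and sample weights 4803.

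With a replicate block the variety counts were 7 (6 of them among the 287), 1 and 0, with fewer residual degrees of freedom. The numbers are not shown to pair these libraries: at day 0 the same-numbered deviations correlated at -0.25, -0.34 and 0.10. The block changed no count of the comparisons with 0 calls. Without the shallow libraries, limma called 0 genes in each comparison of Falstaff conditions, for example 0 of 22763 for UVB against visible light (1928 under an unadjusted p of 0.05) and 0 of 22701 for visible light against day 0 (839). Those fits have 2 libraries per group, and 1 for UVA, and were not tried on simulated data, so that 0 calls there do not separate low power from no response.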

Other observations

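Among the tests of this part, those of low depth, poly(A) selection, UV treatment, UVB exposure, batch tag, library labels, the share of shallow libraries and the splits of the libraries were chosen after the results were seen. Those of genomic DNA, of the authors' column sets and of neighbouring genes were written before.

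Genes with reads in 1 variety of the deep libraries were also read in the 6 shallow libraries, which had not been used to choose them. In Luna bionda UVB 7.5 h replicate 1, 93.9% of the 379 reads on such genes fell on Luna bionda genes (exact 95% interval 91.0% to 96.1%). The other 23 reads fell on 2 genes. In the shallow Falstaff libraries of day 0, UVB, UVA replicate 3 and visible light, 0 reads fell on Luna bionda genes, against 391, 344, 121 and 321 on Falstaff genes. Falstaff UVA replicate 1 had 6 reads on 3 Luna bionda genes and 62 on Falstaff genes. Each shallow library thus carried mostly the genes of its labelled variety.

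Plastid reads lay on few genes. In the shallow libraries 91.1% of the 395915 plastid reads fell on 5 genes, psbA, rps16, psaC, petB and a ribosomal RNA gene. The gene rbcL, which encodes the large subunit of Rubisco, had 452 reads in the 6 shallow libraries and 0 in the 18 deep libraries, which held 516253640 reads. Among plastid genes, 70 had no read in any deep library. The treatment of reads with several matches is not given in the sources used here, and these shares are not read as transcript levels of plastid genes.

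The first pattern weighed is the organelle and noncoding RNA of the 6 shallow libraries. Low depth alone is argued against, since it scales all genes alike and the lowest plastid share of a shallow library was 573.2 times the highest of a deep library. UV treatment is argued against by 2 of the 6 libraries, which came from day 0 and from day 6 under visible light. Library preparation without effective poly(A) selection stays open: 4 of 4 classes that mostly lack poly(A) tails were higher in all 6 libraries than in every deep library, but these classes are the pattern itself and are no independent test. Genomic DNA stays open too, although psbA had 13200 reads or more in each shallow library against at most 1 of the longer rpoC2: with 1 read of rpoC2 over all 24 libraries and 0 of rbcL in the deep ones, the counts appear to miss most plastid genes whatever the source of the reads, so that this planned ratio was void.

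The second pattern is the weak grouping of deep libraries by labelled condition. Within Luna bionda the mean correlation within labelled conditions was 0.9162, below the 95th percentile of random sets (0.9243), and it was 0.9132 with the column sets of the authors' tables, below 0.9242. The deviation of each deep Falstaff library from the mean of the 6 others was projected on a Luna bionda contrast. This contrast was UVB 2.5 h minus visible light, where 1 is the full change. Falstaff visible light replicates 1 and 3 projected at 0.492 and -0.024, and Falstaff UVB replicates 2 and 3 at -0.0527 and -0.169. Falstaff day 0 replicates 2 and 3 projected at -0.194 and -0.0349, and UVA replicate 2 at -0.0173. Such deviations balance out, so that the high value of visible light replicate 1 lowers the others. The negative UVB values are thus not read as an effect of UVB. A UVB response of Luna bionda alone stays open, since libraries of the other variety do not bear on it. The difference between Luna bionda UVB 2.5 h replicates 1 and 2 does not follow tag series or depth, which they share within 1.033 times, but tag series and UVB cannot be told apart between this group and visible light. Wrong labels stay open, for single libraries or for the whole order that the authors' tables follow, and were not tested beyond these correlations.

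The third pattern is the variety difference. The larger number of shallow libraries in Falstaff is argued against as the whole source, since 81.28% of the 1175 genes stayed called without them. Called genes of the same direction were neighbours in the reference order in 142 pairs, where 10000 random draws gave 33.0 on average and 54 at most (permutation p = 0.0001, one-sided, the smallest they can give). This is consistent with stretches of the genome, or families of similar adjacent genes, that differ between the varieties, and reads of an allele that do not match the reference could give the same result. No genome sequence was used here to tell these apart.

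Other splits of the libraries were tested with limma. For the varieties over all 24 libraries, 1 of 100 splits, the real split, gave as many genes (1175, highest other 0). This is the smallest share that 100 splits can give. It takes the libraries as separate units, which the labels do not state. For the interaction, with a real count of 0, 100 of 100 splits gave at least as many by construction, which says nothing on chance. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split was the highest, 1 of 10, for the varieties at day 0 (287, highest other 0), under visible light (228, highest other 0) and at UVB (209, highest other 0). In the comparisons of conditions the real count was 0, so that 10 of 10 splits gave at least as many by construction. The highest other was 36 for Luna bionda UVB 2.5 h against day 0, 2 against visible light and 2335 for UVB 7.5 h against 2.5 h. It was 750 for Falstaff UVA against day 0, 1199 against visible light and 295 against UVB, and 0 for the others. These counts point to a structure of the libraries: the 3 Falstaff splits put the 3 shallow libraries on the same side, and that of 2335 genes put Luna bionda UVB 2.5 h replicate 1 with UVB 7.5 h replicates 2 and 3.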
